A study of Mus musculus with 2 samples.

How the data were processed

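RNA from the hearts of non-transgenic FVB/N mice and of mice with a transgene for cardiac myosin binding protein-C without its C0-C1f region was measured in 1 library each, and each library pooled 3 hearts. Per the labels' protocols, messenger RNA was selected on poly-T beads and made into libraries with a TruSeq kit that keeps strand origin. The deposited values are raw counts of reads per RefSeq transcript, and the submitters' processing notes name STAR, HTSeq and the mm10 genome build. Versions, the annotation and the strand setting of the counting are not given in the sources used here. Counting with a strand setting that does not match the kit would assign reads to the wrong strand, and reads shared by several transcripts of a gene may be left out when counting is done per transcript. Both affect what a count stands for.

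Of 41449 transcript accessions, 41247 were named from a RefSeq gene table and 104 from GENCODE annotation of GRCm38, and counts were summed per gene over 25004 genes. The planned tests spoke of genes, so the sum per gene was the main unit and the count per accession was tried as an alternative. A further 98 accessions had no gene name in the tables used and held 1.81% and 1.66% of the counts; each was kept as its own row. Genes with more than 1 accession were 31.7% of genes but held 15.3% of counts in the non-transgenic and 13.9% in the transgenic library, with a mean of 3.28 and 3.34 counts per gene against 8.46 and 9.62 for other genes. Levels of such genes, Myh6 and Acta1 among them, are therefore not comparable with those of other genes. The number of sample columns not used was 0.

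Coordinates and strands are those of GENCODE release M21 on GRCm38, the assembly also called mm10, for 24686 genes. A gene was called overlapping when an exon of a gene on the opposite strand shared at least 1 bp with its exons, near when such an exon lay within 5 kb, and isolated otherwise. Exons of any annotated transcript of the opposite gene were used, and the spans of the counted transcripts overlapped in 597 of 644 pairs with at least 30 counts on the first gene in both libraries summed. These classes were set up after the counts were seen.

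Library sizes were normalised with TMM factors from edgeR 4.0.16 (0.943 and 1.06) in R 4.3.3. With 1 library per group edgeR's quasi-likelihood test could not be used, and no p-value or standard error was computed. For each gene the ratio of normalised counts, transgenic over non-transgenic, was given an exact 95% Clopper-Pearson interval from the binomial share of its counts, which covers counting error only. A gene was measured if it reached 1 CPM in 1 library, which at these totals of counted reads means a single count. The 4236 genes with more than 3 counts in a library had a ratio. A count of 0 was replaced by a floor of 3 counts in that library, and the fold is then a lower bound against that floor. The lower end of the counting interval also covers the error of the other library's count and lies below it. Genes with a ratio of at least 2 in either direction and an interval on the same side of 1 were counted as higher or lower.

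The 34 gene lists, the comparisons, the alternatives and the rule for the genes named were chosen before the data were examined. The rule took 12 genes whatever their values, the 15 highest and 15 lowest of the genes counted as at least 2-fold apart (ranked by the interval bound nearest to 1, with a mean of at least 5 CPM, without gene models named by a number, sex-linked or haemoglobin genes), and up to 4 members of each list at least 1.5-fold apart, or its 2 most abundant measured members where there were none. Further genes named, such as those of the opposite-strand pairs, Tnni3, Actc1, Tmod1 and Lpl, were chosen after their values were seen. A few genes that the rule takes are not reported here. For each list with at least 3 members with a ratio, the median log2 ratio was given an interval from 1000 resamples of the counts. Its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, describes these libraries and is no test of genotype. A second percentile, matched on 5 expression bins within strand class, was added after the data were seen.

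The calculations were tested on counts simulated, with counting error alone, for the same 25004 genes of this comparison. Of 100 genes simulated at 2-fold with at least 60 counts, 48% were called at least 2-fold, since a gene simulated at the threshold itself falls short of it about as often as not, and 89% at least 1.5-fold, and of 100 simulated at 4-fold all were called. Of 3834 unchanged genes with a ratio 66 were called, 96.5% of the intervals held the simulated ratio, and 94% of random null lists fell in the middle 95% of percentiles. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures used matplotlib 3.10.9. Alternatives were DESeq2 1.42.0 size factors, upper-quartile scaling, total counts alone, other filters on low counts, a prior count of 2, fold thresholds of 1.5 and 4 and no interval, and, added after the data were seen, counts per accession and ratios centred within strand class.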

Results

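Cardiac myosin binding protein-C, the product of Mybpc3, is a thick-filament protein of the heart's sarcomere that regulates contraction. Messenger RNA was sequenced from hearts of FVB/N mice aged 12 weeks, in 1 library from non-transgenic mice and 1 library from mice carrying a transgene for a form of the protein without its C0-C1f region, which lies at the amino terminus. Each library was a pool of 3 hearts, and the comparison asks how transcript levels differed between the transgenic and the non-transgenic heart. With 1 library per group, no difference given here has a replicate check, each describes these 2 libraries, and intervals and floors cover counting error only. The counts summed to 170543 in the non-transgenic and 190824 in the transgenic library, so that 1 count stood for 5.86 and 5.24 CPM, the count scaled to a common library total. At these low totals of counted reads 6725 and 7081 of 25004 genes had a count, and 1697 and 2023 had at least 10. By counting error alone, a gene with 0 counts could lie at up to the floor of 3 counts. This level was 17.6 CPM in the non-transgenic and 15.7 in the transgenic library. Reads left out of the counting or assigned to the other strand are not covered by it. A count of 0 therefore does not show that a gene was barely expressed.

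In both libraries most counts lay on genes whose exons overlap those of a gene on the opposite strand, and the 2 most counted of them lie opposite genes of energy metabolism. Map3k15 (chromosome X, 159988433 to 160123351, plus strand, GRCm38) had the highest count of all genes, 11983 in the non-transgenic and 12037 in the transgenic library. The gene that it overlaps on the minus strand, Pdha1, a subunit of pyruvate dehydrogenase, had 121 and 186. The long non-coding RNA gene A930016O22Rik, opposite the muscle creatine kinase gene Ckm, had 7272 and 6993 counts against 342 and 396 for Ckm. Prpf39 had 2336 and 2592 against 70 and 142 for Fkbp3 on the other strand. Genes that overlap an exon on the opposite strand were 20.7% of all genes and held 68.7% of the counts in the non-transgenic and 63.8% in the transgenic library, a mean of 22.6 and 23.5 counts per gene. Genes with such an exon within 5 kb but no overlap had means of 3.79 and 4.97, and genes with none within 5 kb had means of 1.56 and 2.09. The count of an overlapping gene could not be assigned with certainty to either gene of its pair, which bears on each overlapping gene described. Where no partner is named beside them, Myh6, Myh7, Atp2a2, Pln, Ccn2, Fbxo7, Lratd2, Rnf213, Nit2, Nmrk2, Hsp90b1, Gbp2, Atp2a1, Casq1, Napsa and Arpp21 are overlapping genes too.

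**Figure D1:**
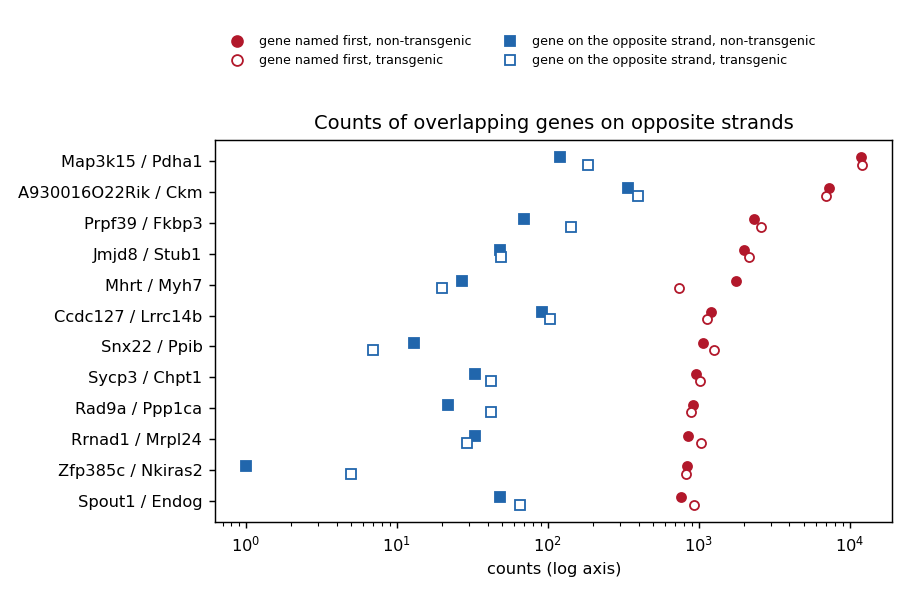
Counts (log axis) of 12 genes among the most counted whose span overlaps that of a counted gene on the opposite strand, ordered by count in the non-transgenic library, with the gene named first as red circles and the gene on the opposite strand as blue squares (filled, non-transgenic library; open, transgenic library). In every pair drawn the gene named first had more counts in both libraries, from Map3k15 with 11983 and 12037 against 121 and 186 for Pdha1.

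Mybpc3 itself (chromosome 2, 91118144 to 91136516, plus strand) was counted at a similar level in both libraries. It had 344 counts in the non-transgenic and 398 in the transgenic library, a ratio of 0.920 after normalisation (95% counting interval 0.794 to 1.07), and the sign of its log2 ratio flipped from -0.12 to 0.05 under scaling by total counts alone. A count per gene does not separate transcripts of the transgene from those of the endogenous gene, so this value checks nothing about the labels. Whether the count of Mybpc3 follows its expression also depends on how reads were assigned to strands.

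Among 8199 measured genes, 4236 had a ratio and could be called. Of these, 105 were at least 2-fold higher and 157 at least 2-fold lower in the transgenic library with a counting interval on the same side of 1. In the counts simulated with counting error alone, 66 of 3834 unchanged genes with a ratio were called as well. Variation between animals or preparations was not simulated, so 66 is no estimate of the false calls between these libraries. The genes most clearly higher in the transgenic library included the metabolic enzyme gene Got1, the mitochondrial carrier gene Slc25a5 and the complex I gene Ndufb6. Those most clearly lower included Pdk4, which restrains pyruvate oxidation, the amino acid transporter genes Slc7a11 and Slc38a9, and Mhrt, a long non-coding RNA gene opposite the myosin heavy chain gene Myh7. Got1, the cytosolic aspartate aminotransferase, was 2.86-fold higher (counting interval 2.0 to 4.17) with 40 and 144 counts. Slc25a5, an ADP/ATP carrier of the inner mitochondrial membrane, was 4.77-fold higher (1.83 to 15.7). Ndufb6, a subunit of respiratory complex I that overlaps Smim27, was 3.34-fold higher (1.65 to 7.46). The lipid droplet protein gene Plin3 was 3.75-fold (1.63 to 10), the tetraspanin gene Tspan3 4.93-fold (1.90 to 16.2), Pcp4l1 2.75-fold (1.76 to 4.44) and the prostaglandin D synthase gene Ptgds 2.83-fold higher (1.60 to 5.28). Itgad, an integrin subunit gene that overlaps 4931431B13Rik and the cytochrome oxidase gene Cox6a2 (82 and 109 counts), was 2.58-fold higher (1.84 to 3.69), and Prss57, opposite Fstl3, was 2.27-fold higher (1.62 to 3.22). Serping1, an inhibitor of complement, had 1 and 18 counts, a ratio of 14.3 (2.26 to 596), and Cdnf had 1 and 15, a ratio of 11.9 (1.83 to 502). Apeh and Cnih4 had 0 counts in the non-transgenic library and were at least 3.18-fold and 2.92-fold higher against the floor, with lower ends of the counting interval at 2.21 and 2.0. Rps18-ps4, named as a ribosomal protein pseudogene and annotated as a long non-coding RNA gene on chromosome 13 (97751112 to 97760965) opposite Gm10260, had 1 count against 688, a ratio of 547 (97.9 to 21637). Its count is uncertain, as it could not be assigned to either gene of the pair.

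Mhrt (chromosome 14, 54968787 to 54974349, plus strand) had 1778 counts in the non-transgenic and 737 in the transgenic library and was 3.03-fold lower (counting interval 2.78 to 3.31). Its overlap with Myh7 spans 484 bp. Pdk4 (chromosome 6, 5483351 to 5496309), with no gene on the opposite strand within 5 kb, was 4.09-fold lower (2.56 to 6.76) with 78 and 24 counts. Slc7a11, the cystine-glutamate exchanger, had 18 counts against 0 and was at least 7.55-fold lower against the floor, with the lower end of the counting interval at 5.53. The lysosomal amino acid transporter gene Slc38a9 had 24 against 2, a ratio of 0.0663 (0.00759 to 0.267). Col8a1, a collagen gene, was 5.97-fold lower (1.99 to 24.1). Trir and the DNA repair gene Xpa, both with 0 counts in the transgenic library, were at least 4.19-fold and 3.35-fold lower, with lower ends at 2.82 and 2.15. Of the remaining genes, all with a gene on the opposite strand, Rab11b (opposite Gm17251) was 4.56-fold lower (2.59 to 8.50) and Spg11 (opposite Eif3j1) 3.77-fold lower (2.32 to 6.34). Cdc23, opposite Kif20a, was 5.75-fold (2.49 to 15.4), Exosc9, opposite Ccna2, 5.03-fold (2.0 to 15), Lratd2 5.57-fold (2.41 to 15) and Rnf213 5.53-fold lower (2.04 to 18.7). Fbxo7 had 13 counts against 1, a ratio of 0.0612 (0.00144 to 0.407), and Nit2 had 11 against 1, a ratio of 0.0723 (0.00168 to 0.497). The higher calls made up 40.1% of all calls, and this split turned to 57.5% with DESeq2 size factors and 63.7% with total counts alone, which shifted the median log2 ratio of all genes by 0.11 and 0.17. Among the genes named by the fixed rule that had a ratio, Mybpc3 and the calcium-binding protein gene Hrc were the only ones to change sign under another scaling.

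The ratio between the libraries also went with the strand class of a gene. Among genes with at least 30 counts in both libraries summed, the median log2 ratio was -0.26 (95% interval from resampled counts -0.29 to -0.24) for 754 overlapping genes and 0.18 (0.12 to 0.28) for 235 genes with no gene on the opposite strand within 5 kb. The 345 genes in between had a median of 0.06 (0.00 to 0.12). Calls of at least 2-fold were split in the same order. Higher and lower calls were 27 and 82 among all overlapping genes, 38 and 49 among near genes and 39 and 22 among isolated genes. The split of calls therefore went with strand class. An excess of lower calls remained when ratios were centred within strand class (86 higher and 150 lower). As given above, it turned to an excess of higher calls with DESeq2 size factors or total counts alone. The difference of 0.44 (0.38 to 0.55) between the outer classes is the same under any scaling, and each gene list was therefore also set against random lists matched on strand class.

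**Figure D2:**
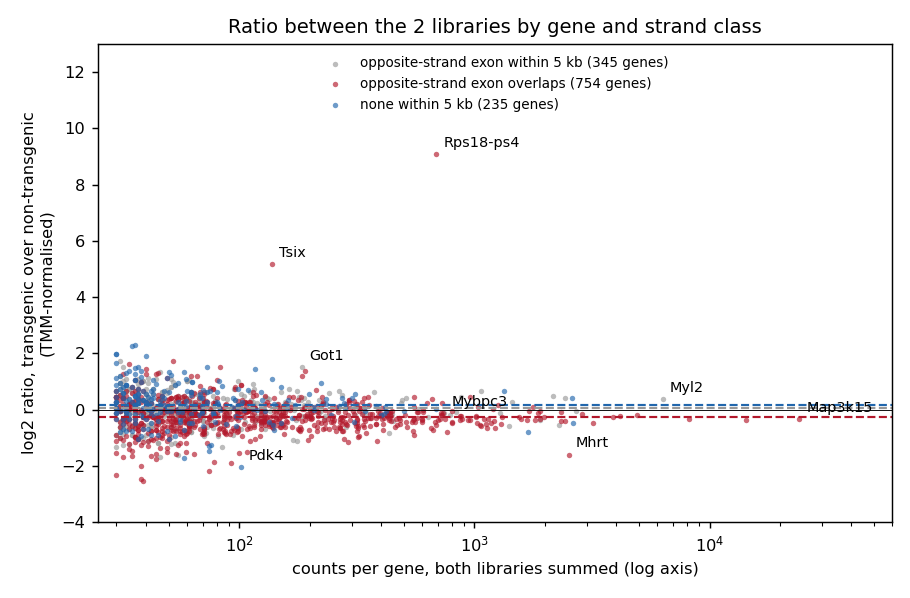
Log2 ratio of transgenic over non-transgenic normalised counts (y axis) against counts summed over both libraries (x axis, log scale) for genes with at least 30 counts, 1 point per gene, coloured by strand class, with dashed lines at the class medians of -0.26 (overlapping), 0.06 (within 5 kb) and 0.18 (none within 5 kb). Tsix, with 0 counts in the non-transgenic library, is drawn at its lower bound.

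Genes of the thin filament and Z-disc were counted higher in the transgenic library as a group, while the median of the thick-filament genes lay near a ratio of 1. A list member counted as higher or lower if it was at least 1.5-fold apart with a counting interval on the same side of 1, and as neither otherwise. Results for every list cover only its members with a ratio, here 11 of 21 for the thin filament and Z-disc and 7 of 14 for the thick filament. Of 11 thin-filament and Z-disc genes with a ratio, 2 were at least 1.5-fold higher, none was that much lower and 9 were neither. Tnnc1, cardiac troponin C, was 1.59-fold higher (counting interval 1.39 to 1.81) with 357 and 712 counts, and the actin-filament nucleator gene Lmod3 was 1.66-fold higher (1.08 to 2.62). Tnni3, cardiac troponin I, at 1.40-fold (1.28 to 1.53) and Actc1, cardiac actin, at 1.34-fold (1.23 to 1.45) were below that size. Tmod1, which caps actin filaments and overlaps Tstd2, went the other way with 288 and 269 counts, a ratio of 0.743 (0.627 to 0.880). The median log2 ratio of the list was 0.42 (0.15 to 0.53), at percentile 99.99 of random lists matched on expression and 98.3 of those matched on strand class too. For the 7 thick-filament and M-band genes with a ratio, of which none passed 1.5-fold beyond its counting interval, the median was 0.08 (-0.17 to 0.21), at percentiles 91.6 and 76.8. Myl2, the ventricular regulatory light chain, was 1.29-fold higher (1.23 to 1.36) with 2405 and 3916 counts. Myh6 had 0 and 1 counts, and no ratio was given.

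Genes of the hypertrophic, or fetal, programme did not move together. Of 7 with a ratio, among 16 list members, 1 was at least 1.5-fold higher, 1 lower and 5 neither. Nppa, which encodes atrial natriuretic peptide and overlaps Gm13054, was 2.74-fold higher (1.27 to 6.54) with 9 and 31 counts, whereas the nicotinamide riboside kinase gene Nmrk2 was 1.63-fold lower (1.10 to 2.44). Myh7 had 27 and 20 counts, a ratio of 0.589 (0.313 to 1.09), and Ccn2 had 19 and 28, a ratio of 1.17 (0.632 to 2.22). Nppb and Postn had no count in either library and Acta1 had 0 and 1. The list's median log2 ratio was -0.67 (-0.84 to 0.05), at percentiles 2.13 and 2.79.

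Collagen and matrix genes had a lower median in the transgenic library, at low counts. Of 11 extracellular matrix genes with a ratio, among 33 list members, none was at least 1.5-fold higher, 2 were lower and 9 were neither. The 2 were Col8a1 and Col3a1, a fibrillar collagen gene that was 2.07-fold lower (1.02 to 4.34) with 23 and 14 counts. Col1a1 had 8 and 5 counts, a ratio of 0.497 (0.128 to 1.72). The median was -0.65 (-1.33 to -0.01), at percentiles 3.52 and 0.865.

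Calcium handling and adrenergic signalling genes with a ratio, 6 of 17 and 8 of 18 list members, had medians near a ratio of 1. The calcium handling genes Slc8a1, Cacna1c, Casq2 and Camk2d had no count in either library, so these medians do not describe the whole lists. None of 6 calcium handling genes with a ratio passed 1.5-fold beyond its counting interval. Hrc had 595 and 683 counts, a ratio of 0.913 (0.816 to 1.02), and the ryanodine receptor gene Ryr2 had 129 and 185, a ratio of 1.14 (0.906 to 1.44). Atp2a2, the sarcoplasmic reticulum calcium pump, had 3 and 4 counts and Pln, its inhibitor, 2 and 1. The median of -0.01 (-0.28 to 0.25; percentiles 69.2 and 39.5) was positive with DESeq2 size factors and with total counts. Of 8 adrenergic and protein kinase A genes, 7 were neither, and the kinase anchor gene Akap6 was 2.10-fold higher (1.11 to 4.21); the median of -0.02 (-0.44 to 0.56; percentiles 43.8 and 42.0) flipped under the same scalings. Of 11 ion channel and gap junction genes, 2 were lower and 9 neither. The sodium channel subunit gene Scn4b had 13 and 3 counts, a ratio of 0.183 (0.0335 to 0.668), and the potassium channel gene Kcnj11 was 1.92-fold lower (1.07 to 3.50), while the list's median was 0.25 (-0.59 to 0.62; percentiles 64.8 and 65.7).

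Nuclear genes of oxidative phosphorylation were counted higher in the transgenic library as a group, and several genes of fatty acid use were counted lower. Whether these counts follow expression depends on how reads were assigned to strands. Of 28 oxidative phosphorylation genes with a ratio, 5 were at least 1.5-fold higher, none was that much lower and 23 were neither. The cytochrome oxidase gene Cox8b was 1.68-fold (1.12 to 2.55), the succinate dehydrogenase gene Sdhd 1.64-fold (1.05 to 2.61) and Ndufa4 1.54-fold higher (1.24 to 1.92), and Cox6b1 had 1 and 10 counts, a ratio of 7.95 (1.13 to 345). The median was 0.32 (0.19 to 0.44), above all 10000 random lists matched on expression and at percentile 99.97 of those matched on strand class. Among genes opposite list members, Pdzd9, which overlaps Uqcrc2, had 419 and 383 counts, a ratio of 0.727 (0.631 to 0.837), against 1.27 (0.996 to 1.62) for Uqcrc2 itself, whereas Itgad was higher and Cox6a2, opposite it, had a ratio of 1.06 (0.786 to 1.43). Eef1b2, with an annotated exon overlap of 9 bp with Ndufs1 but no overlap between the spans of the counted transcripts, was higher too. It had 25 and 52 counts, a ratio of 1.65 (1.01 to 2.78), and Ndufs1 had no count in either library. Of 20 fatty acid genes, none was higher, 4 were lower and 16 were neither. They included Pdk4, the uncoupling protein gene Ucp3, 2.52-fold lower (1.12 to 6.02), and the thiolase gene Acaa2, 1.53-fold lower (1.21 to 1.95). Other members went the other way, such as the lipoprotein lipase gene Lpl at 1.32-fold higher (1.22 to 1.43), and the median was -0.15 (-0.32 to 0.07; percentiles 43.9 and 6.92), turning to 0.02 with total counts. Of 6 glucose and glycolysis genes, Slc16a1, a lactate transporter, was 2.02-fold higher (1.29 to 3.24) and 5 were neither, with a median of 0.25 (-0.02 to 0.61; percentiles 88.9 and 90.7). No mitochondrially encoded gene was in the tables used.

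**Figure D3:**
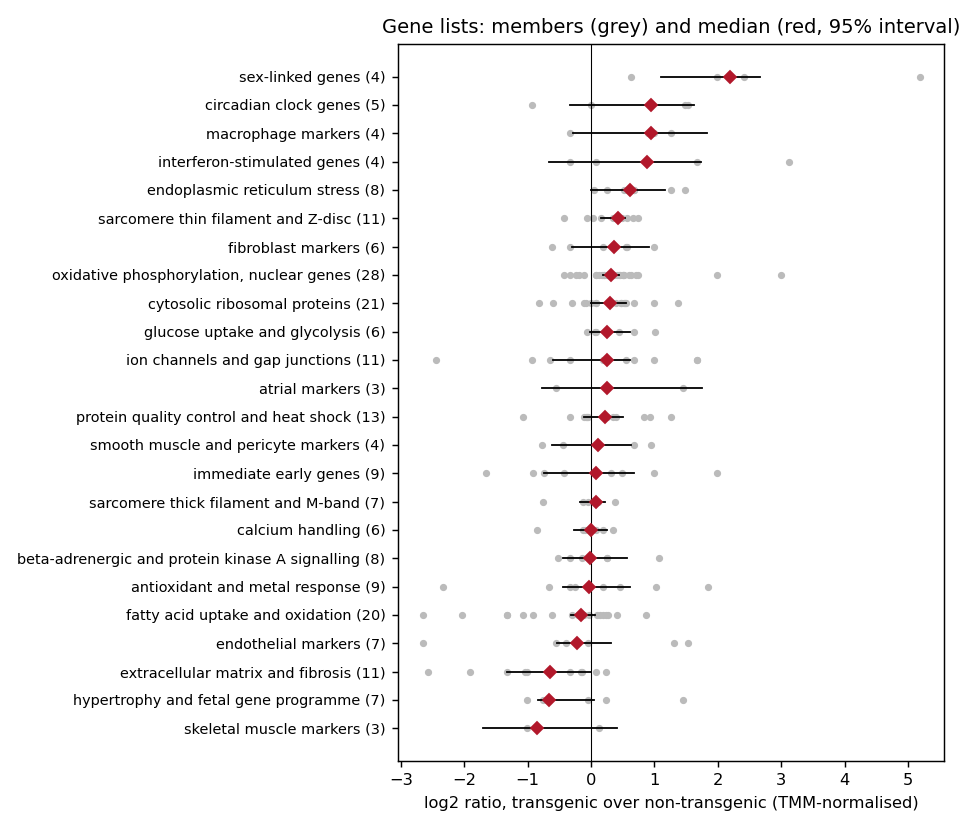
Log2 ratio of transgenic over non-transgenic normalised counts for the gene lists with at least 3 members with a ratio (number in brackets), with members as grey points, the list's median as a red diamond and its 95% interval from resampled counts as a black line. The thin filament and Z-disc list (0.42), the oxidative phosphorylation list (0.32), the sex-linked list (2.20) and, with a lower end of 0.0027, the endoplasmic reticulum stress list (0.62) have intervals above 0; members with 0 counts in a library, such as Tsix, are drawn at their bound.

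Most ribosomal protein and stress genes were neither higher nor lower by 1.5-fold beyond their counting intervals. Of 21 cytosolic ribosomal protein genes, 2 were at least 1.5-fold higher, among them Rplp1 at 2.58-fold (1.14 to 6.60), and 19 were neither, with a median of 0.29 (-0.01 to 0.55; percentiles 97.7 and 94.5). Of 13 protein quality control genes, 2 were higher, 1 lower and 10 neither. The atrophy-related ubiquitin ligase gene Fbxo32, which overlaps Gm15943, was 2.39-fold (1.13 to 5.47) and the small heat shock protein gene Hspb8 1.77-fold higher (1.10 to 2.94), while Hspd1 had 5 counts against 0; the median was 0.23 (-0.11 to 0.50; percentiles 92.8 and 85.0). None of 8 endoplasmic reticulum stress genes passed 1.5-fold beyond its counting interval. The chaperone genes Hsp90b1 and Calr had ratios of 1.04 (0.829 to 1.30) and 1.19 (0.888 to 1.61), and the median of 0.62 (0.00 to 1.17; percentiles 90.8 and 95.4) rested mostly on genes with few counts. Of 9 antioxidant genes, catalase, Cat, was 1.59-fold lower (1.06 to 2.41) and 8 were neither, with a median of -0.04 (-0.44 to 0.61; percentiles 41.3 and 24.5) that was positive with DESeq2 size factors and with total counts. None of 9 immediate early genes passed 1.5-fold beyond its counting interval. Dusp1 had 29 and 27 counts and Klf4 13 and 23, and the median was 0.08 (-0.75 to 0.67; percentiles 42.1 and 35.1), turning to -0.17 when ratios were centred within strand class.

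Genes of the circadian clock differed in opposite directions. Dbp, a clock output transcription factor gene opposite Sphk2, was 2.87-fold higher (1.68 to 5.14) with 18 and 65 counts. Nr1d1, a repressor of the clock opposite Thra, was 1.91-fold lower (1.52 to 2.40) with 194 and 128 counts, and the other 3 of 5 genes with a ratio were neither. The median was 0.94 (-0.33 to 1.62), at percentiles 99.6 and 99.3. Of 4 interferon-stimulated genes, Gbp2 had 1 and 11 counts, a ratio of 8.75 (1.27 to 376), and 3 were neither, with a median of 0.88 (-0.67 to 1.73; percentiles 87.8 and 87.2).

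Most markers of the heart's other cells and of the atria were neither, and the few that passed 1.5-fold were higher in the transgenic library. Of 7 endothelial genes with a ratio, 2 were at least 1.5-fold higher and 5 neither. The water channel gene Aqp1 was 2.88-fold (1.29 to 7.30) and the growth factor receptor gene Flt1 2.48-fold higher (1.09 to 6.37), while the list's median was -0.22 (-0.54 to 0.31; percentiles 32.6 and 7.20). The pericyte marker Rgs5 was 1.92-fold higher (1.43 to 2.61) with 65 and 157 counts, and the other 3 smooth muscle and pericyte genes were neither, with a median of 0.12 (-0.62 to 0.62; percentiles 71.5 and 77.2). None of 6 fibroblast genes passed 1.5-fold beyond its counting interval. Dpt had 14 and 26 counts and Lamc1 14 and 20, and the median was 0.36 (-0.30 to 0.91; percentiles 80.5 and 79.3). Nor did any of 4 macrophage genes, of which Lyz2 had 6 and 15 counts and Mrc1 3 and 9, with a median of 0.94 (-0.28 to 1.83; percentiles 93.0 and 89.2). Of 3 atrial genes, only Nppa passed, and the median was 0.25 (-0.78 to 1.76; percentiles 77.0 and 72.5).

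The sex-linked genes Xist and Tsix, which overlap each other by 1980 bp, had counts in the transgenic library alone. Tsix (chromosome X, 103431517 to 103484957, plus strand) had 0 counts against 137 and was at least 36.3-fold higher against the floor of 3 counts, with the lower end of the counting interval at 29.1. Xist (chromosome X, 103460366 to 103483254, minus strand), the RNA that silences an X chromosome in female cells, had 0 against 20 and was at least 5.30-fold higher, with the lower end at 3.93. The other 2 of 4 genes with a ratio were neither, and the median with both genes at their bounds was 2.20 (1.11 to 2.66), above all 10000 random lists of both kinds. All Y-linked genes together had 1 count in the non-transgenic and 0 in the transgenic library. The labels used do not give the sex of the animals, so a difference in sex between the pools is not separated from the transgene in any comparison given here.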

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

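No test of an explanation was run in this part, and the value was looked at after the counts were seen. A transcript with no gene name in the tables used, NR_046233, took no part in the comparisons of named genes and had a higher level in the transgenic library than in the control. It had 96 counts in the non-transgenic and 191 in the transgenic library, or 597 and 944 normalised CPM, a ratio of 1.58 (95% counting interval 1.23 to 2.04). The other 2 unnamed transcripts with at least 30 counts in both libraries summed were lower in the transgenic library, NM_001282148 with 2864 and 2855 counts, a ratio of 0.793 (0.752 to 0.835), and NM_001308498 with 117 and 106, a ratio of 0.720 (0.549 to 0.945).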

How the results depend on the processing

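The alternatives of counts per accession and of ratios centred within strand class were chosen after the data were seen. With total counts alone, 167 genes were higher and 95 lower, against 105 and 157, and the list medians moved to 0.25 for the thick filament, 0.59 for the thin filament and 0.49 for oxidative phosphorylation. With DESeq2 size factors the thin filament median was 0.53, and 150 genes were higher and 111 lower. These follow from the shift that either scaling gives to every gene. A fold threshold of 1.5 gave 250 lower genes, a threshold of 4 gave 32 higher and 41 lower, and without an interval 564 and 563 passed, since fewer or more genes meet the condition. Centring within strand class moved the fatty acid median to -0.34, by its construction, and gave 86 higher and 150 lower genes, of which 75 and 126 were shared with the main calls. Upper-quartile scaling (100 and 163), a prior count of 2 (103 and 147) and counts per accession (103 and 156) stayed within 1.5 times of the counts of calls. A minimum of 5 CPM and no minimum moved nothing, because 1 count exceeds 5 CPM in both libraries. Leaving out mitochondrially encoded genes was not run, as none was in the tables used. No paired analysis was possible because each group had 1 library and the labels give no replicate numbers. Among 81 genes with a ratio that the naming rule takes, 4 moved beyond their counting interval with total counts, 1 with DESeq2 size factors and 3 with centring. The low totals of counted reads limit single-gene ratios, since 4236 of 8199 measured genes had more than 3 counts in a library.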

Other observations

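The tests of opposite-strand pairs, of counting without strand, of gene-dense regions, of the share of reads on the other strand, of sarcomere genes (against ribosomal protein genes, and left out of the classes) and of the sex-linked genes were chosen only after the result was seen, and the test of olfactory receptor genes was written before. Genes of cells and tissues that could have been taken along with the heart were barely counted in either library. Low counts cannot show that such cells were absent, since reads may have been left out or assigned to the other strand. The haemoglobin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt had no count in either library, and neither had Tnnt2 of the thin filament list. Skeletal muscle genes were the most counted of them, with 3 genes with a ratio and none past 1.5-fold beyond its counting interval; Atp2a1 had 8 and 11 counts and Casq1 10 and 7, and the median was -0.85 (-1.71 to 0.41; percentiles 6.05 and 11.6). No ratio could be given for any lymphocyte, neutrophil, Schwann cell, epicardial, lung or thymus marker. The lymphocyte markers Cd4 and Ms4a1 had 0 and 1 counts each, the neutrophil markers Mmp9 and Lcn2 had 2 and 0 and 0 and 1, and Dbh, of sympathetic nerves, had 2 and 0. The epicardial markers Wt1 and Aldh1a2 had 1 and 1 and 1 and 0 counts, the lung marker Napsa 0 and 1, and the thymus markers Cd1d1 and Arpp21 0 and 2 and 1 and 0. The adipocyte genes Cidea and Adipoq had 7 and 5 and 0 and 1 counts, with 1 member with a ratio, and of the red cell genes 1 had a ratio; neither passed 1.5-fold beyond its counting interval. Of 2 cell cycle genes with a ratio, the proliferation marker Mki67 had 5 counts against 0 and was at least 2.10-fold lower against the floor, with the lower end of the counting interval at 1.15, and the other was neither.

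Most counts lay on genes with an annotated gene on the opposite strand, and a candidate explanation is that reads were counted on the strand opposite to the transcript, which can happen when a stranded kit is counted with the other setting. Among 75 overlapping pairs of a non-coding and a protein-coding gene with 1 accession each, the non-coding gene held more counts in 63, or 84.0% (exact 95% Clopper-Pearson interval 73.7 to 91.4%). An earlier test, of heart genes on the lists against the unlisted genes that overlap them, had the unlisted gene ahead in 6 of 16 pairs (37.5%, 15.2 to 64.6%), which decided nothing, and the non-coding pairs were chosen after it with their own count already seen. Counting without strand leaves shared reads out, but overlapping genes held 12.6 times the mean count of isolated genes, and gene-dense regions would raise near genes alike, but overlapping genes held 5.25 times their mean count. If the explanation holds, the 3.03-fold lower count of Mhrt may report on Myh7, whose own counts of 27 and 20 gave a ratio of 0.589 (0.313 to 1.09), and this stays a hypothesis.

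Isolated genes had a median log2 ratio higher by 0.44 than overlapping genes, and a larger share of reads on the strand less often counted in the transgenic library is a candidate explanation. In 52 pairs whose overlapping gene held at least 3 times the counts, the gene's own counts had the higher log2 ratio in 35, with a median difference of 0.23 (0.09 to 0.41). Reads from genomic DNA would fall on silent genes too, but 1106 olfactory receptor genes held 19 counts in all, 0.0047 of the mean count of isolated genes. Whether sarcomere genes were higher with the transgene stays open. For 13 sarcomere genes without an overlapping gene minus 17 such ribosomal protein genes, the median difference was -0.022 (-0.38 to 0.35). Leaving sarcomere genes out, tried later, removed 5 isolated and 4 overlapping genes. The class difference was then 0.446 (0.386 to 0.556) over 230 and 750 genes. The class difference was therefore present without the listed sarcomere genes. So few genes hardly move a median, so leaving them out could not decide whether sarcomere genes were higher with the transgene. The higher medians of the thin filament and oxidative phosphorylation lists may be partly technical. Centring ratios within strand class left them at 0.34 and 0.34. It shifts all genes of a class alike, so it cannot remove a technical difference between genes of the same class. Counts opposite Uqcrc2 (0.727 on Pdzd9, against 1.27 on Uqcrc2) and Pdha1 (0.799 on Map3k15, against 1.22 on Pdha1) were lower. Those on Itgad opposite Cox6a2 (2.58) and on Eef1b2 opposite Ndufs1 (1.65) were higher. Itgad overlaps Cox6a2 by 70 bp but 4931431B13Rik by 388 bp, and the counted spans of Eef1b2 and Ndufs1 do not overlap. Neither count therefore need report on the listed gene.

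Xist and Tsix had counts in the transgenic library alone, and hearts of female mice in that pool but not in the other are a candidate explanation. A larger share of reads on the other strand would raise Tsix no more than other genes, but the lower end of the counting interval of its log2 ratio, 4.86, lay 2.75 above the upper end, 2.12, of the range that holds the middle 95% of isolated genes. Y-linked genes would show males in the non-transgenic pool, but 52 of them held 1 count there and 0 in the transgenic library, so that sex and transgene cannot be told apart by them. Under the explanation of counts on the opposite strand, the 137 counts of Tsix may be Xist RNA. A difference in sex between the pools could also contribute to any other difference and was not tested further.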
